A study of Homo sapiens with 9 samples.

How the data were processed

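Gene expression was measured by RNA sequencing in 9 libraries of UACC-812 cells, 3 each with a scramble siRNA, siRNA 1 and siRNA 2 against TINCR. Each file listed one FPKM value per gene, a unit given per the file headers, with 2 decimals. Per the submitters' processing notes, reads were aligned with Bowtie2 and quantified with RSEM on GRCh38.p12. The files held no counts, so depth was unknown and no interval from counting was given.

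Of 18064 genes, 17748 were matched to RefSeq gene IDs, 17324 were protein-coding and 268 long noncoding. Symbols turned into dates by a spreadsheet numbered 12, and all 12 were restored from their gene ID. The files held 0 mitochondrially encoded genes and 0 entries for TINCR.

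Values were used as log2(FPKM + 1) with no further scaling. Genes with at least 1 FPKM in at least 3 libraries were tested, 12317 in all. One limma-trend fit (limma 3.58.1, R 4.3.3) held all 9 libraries in 3 groups, with Benjamini-Hochberg adjustment at 0.05. SDs were over 3 libraries in FPKM, and SEs were limma's on the log2 scale. The fit for FPKM, the filter, the comparisons, 37 gene lists and the rule for named genes were chosen before the data were examined, and the design expected counts with FPKM as its stated fallback. Gene lists with at least 3 tested members, 34 of them, were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the lists. Members were counted over all genes and adjusted over the list alone.

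Named genes were TINCR and the 4 ERBB receptors, the 12 highest and 12 lowest shared genes by the smaller fold change, the 8 highest and 8 lowest of each siRNA and of the direct comparison, and up to 4 genes per list. The shared genes and those picked from each comparison needed a mean of at least 1 FPKM in the higher group and a symbol that is no pseudogene or clone name. TINCR, the ERBB receptors and the genes picked from lists did not. Other named genes are marked as chosen after their values were seen.

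Shared genes passed with both siRNAs in the same direction. Chance overlap was simulated 100 times with unchanged groups that share controls. On simulated data with 200 changed genes, the test recovered 33.2% and 33.6% of changes of 0.2 on the log2 scale for siRNA 1 and siRNA 2, 91.2% and 90.8% of changes of 0.4, and 100% of 0.8, with 6.8 and 10.8 false calls on average. These rates hold for 200 changed genes of 12317 with independent noise. In the data 7766 genes were called with siRNA 1, so the adjusted cutoff was less strict and the rates do not carry over.

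Windows of 50 neighbouring tested genes, 25 genes apart, were compared with 1000 shuffles of gene positions over 12262 genes, and intervals of median shifts came from 2000 bootstrap draws. This scan and its alternatives were chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest. Alternatives planned before were a pseudocount of 0.1, no filter, a mean of at least 1 FPKM, only the 6 libraries compared, the replicate number as a block, each replicate left out, a fold minimum and an adjusted p of 0.01. Median-ratio scaling, quantile normalization, subtracting the median of neighbouring genes and leaving out chromosomes 2 and 20 were added after seeing the data. TINCR could not be measured, and tests that need counts were not run.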

Results

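RNA was sequenced from UACC-812, a human breast cancer cell line described as ERBB2-amplified, 48 h after transfection with a scramble siRNA or with 1 of 2 siRNAs against the long noncoding RNA TINCR, named siRNA 1 and siRNA 2 here. There were 9 libraries, 3 in each of 3 groups. The values were FPKM (fragments per kilobase of transcript, scaled to the fragments of the library), summing to between 394081 and 419025 per library over all listed genes. Between 11812 and 11856 genes reached 1 FPKM in the scramble libraries, and between 12091 and 12139 did so in the siRNA libraries. The files held no read totals, so the depth was unknown. Pearson's r of log2 values across genes was 0.996 to 0.997 between libraries of the same group, 0.995 to 0.997 between both siRNAs, and 0.956 to 0.961 between scramble and siRNA libraries. Genes are not independent replicates, and these correlations describe the libraries only.

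The first question was whether the siRNAs lowered their target. TINCR had 0 entries among the listed genes, so its level was not analysed here and the labels could not be checked against it.

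The series title names EGFR and receptor tyrosine kinases, so the receptors of the ERBB family were compared next. EGFR (gene ID 1956, chromosome 7, 55019032 to 55207338, GRCh38.p12), the receptor for epidermal growth factor, was at 56.9 ± 3.27 FPKM (SD, n = 3) in scramble, 35.9 ± 1.53 with siRNA 1 and 36.3 ± 0.538 with siRNA 2. Its log2 fold change was -0.65 (SE 0.046, limma adjusted p = 1.16e-07) with siRNA 1 and -0.63 (SE 0.046, adjusted p = 1.53e-07) with siRNA 2. Its neighbouring genes had medians of -0.05 and -0.04 relative to the median of all genes. ERBB2 (gene ID 2064, chromosome 17, 39688084 to 39728662) rose from 24.0 ± 1.93 to 29.9 ± 1.6 and 29.6 ± 0.467 FPKM, with adjusted p = 0.000447 and 0.000631 in limma. ERBB3, the partner of ERBB2 in neuregulin signalling, rose from 7.51 ± 0.555 to 10.1 ± 0.368 and 9.29 ± 0.435 FPKM, by 0.38 and 0.27 on the log2 scale. Subtracting the regional median, a setting chosen after the results were seen, left ERBB2 at 0.17 and 0.20 and ERBB3 at 0.23 and 0.15, all still called. This setting also removes the median fold change of all genes, 0.06 with each siRNA. Median-ratio scaling, which removes only the latter, left ERBB2 at 0.24 and 0.23 and ERBB3 at 0.32 and 0.21. Adjusted over the list alone, 2 of the 3 tested receptors were higher and 1 was lower with each siRNA, the same counts as over all genes. ERBB4 was below the filter, at 0.14 to 0.17 FPKM in scramble and 0.03 to 0.06 in the siRNA libraries.

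Of 8 tested ERBB ligands, 4 rose and 4 fell with siRNA 1, and 3 rose and 4 fell with siRNA 2, with the same counts adjusted over the list alone. TGFA, a ligand of EGFR, fell from 91.6 ± 3.06 to 14.6 ± 1.17 and 16.9 ± 0.483 FPKM. TGFA lies on the part of chromosome 2 described further on, where its neighbours had medians of -0.36 and -0.33 relative to all genes. HBEGF fell from 53.2 ± 0.596 to 18.04 ± 0.788 and 18.1 ± 1.01 FPKM, while EPGN rose from 6.11 ± 0.406 to 10.6 ± 0.458 and 10.5 ± 0.572. Of 21 other receptor tyrosine kinases, 9 rose and 3 fell with each siRNA, over all genes and adjusted over the list alone. Median-ratio scaling turned this to 9 and 6 with siRNA 1 and 8 and 5 with siRNA 2. EPHA2 fell from 125 ± 6.71 to 53.7 ± 1.16 and 55.5 ± 0.759 FPKM, AXL fell from 97.0 ± 2.41 to 51.3 ± 1.43 and 58.9 ± 0.807, and DDR1 rose from 32.6 ± 1.97 to 68.7 ± 1.82 and 65.1 ± 2.0. Neither the ligands nor the other receptors passed camera (adjusted p = 0.464 and 0.74 with siRNA 1, 0.484 and 0.551 with siRNA 2).

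With siRNA 1, the collagenase MMP1 (gene ID 4312, chromosome 11, 102789910 to 102798235) fell from 570.1 ± 4.46 to 5.99 ± 0.306 FPKM (n = 3), a log2 change of -6.35 (SE 0.043). The stromelysin MMP10, next to it on chromosome 11, fell from 134.6 ± 3.26 to 5.20 ± 0.155 FPKM. The membrane linker moesin, MSN, fell from 72.9 ± 1.22 to 3.98 ± 0.205 FPKM. S100A8 (gene ID 6279, chromosome 1, 153390032 to 153422583), a calcium-binding protein of inflamed epithelium, rose from 7.33 ± 1.15 to 197 ± 5.84 FPKM, a log2 change of 4.58 (SE 0.074). IGFBP3, which binds insulin-like growth factors, rose from 27.2 ± 0.591 to 428 ± 11.3 FPKM, and the basal keratin KRT14 rose from 0.52 ± 0.121 to 23.7 ± 0.535. KRT14 has close paralogs, among which short reads can be misplaced. In limma, 4731 of 12317 tested genes were higher and 3035 lower at an adjusted p under 0.05, and 339 and 233 of these changed by at least 1 on the log2 scale. Median-ratio scaling turned the split to 3862 higher and 3884 lower.

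With siRNA 2, MMP1 was at 5.42 ± 0.236 FPKM (log2 change -6.48, SE 0.043), MMP10 at 4.47 ± 0.261 and MSN at 4.15 ± 0.364, all far below scramble. S100A8 was at 139 ± 3.63 FPKM (log2 change 4.08, SE 0.074), IGFBP3 at 385 ± 2.72 and KRT14 at 19.4 ± 2.04. TNFSF10, the death ligand TRAIL, rose from 2.67 ± 0.437 to 37.0 ± 0.296 FPKM, and IL20RB, a subunit of receptors for the interleukin 20 family, rose from 2.69 ± 0.254 to 37.9 ± 1.43. In limma, 4756 genes were higher and 3003 lower, of which 344 and 216 changed by at least 1 on the log2 scale. Median-ratio scaling turned the split to 3866 higher and 3890 lower. The labels do not say that replicates were separate cultures, so p-values measure only the spread between libraries, which may be technical.

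Most genes called with one siRNA were called with the other in the same direction. THBS1, an extracellular matrix glycoprotein, fell from 438 ± 1.82 to 51.0 ± 1.85 and 56.1 ± 0.478 FPKM. SERPINB2, an inhibitor of plasminogen activators, fell from 213 ± 10.8 to 23.1 ± 1.06 and 24.9 ± 0.423. KRT17 rose from 116 ± 2.60 to 1001 ± 41.1 and 867 ± 12.3 FPKM, and KRT5 from 199 ± 3.04 to 1318 ± 52.0 and 1210 ± 3.56. The 12 highest shared genes also included SERPINB3, SERPINB13, S100A7, WNT10A, SPANXC and SPANXA1, and reads of SPANX genes cannot be placed with certainty among their near-identical copies. The 12 lowest also included TMEM200A, ESM1, ANKRD1 and EMC10, with GPAT2 and CYP1B1 on the shifted part of chromosome 2 and TGM2 on chromosome 20.

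In limma, 4157 genes were higher and 2572 lower with both siRNAs, against 1827 and 740 if the calls were independent. Median-ratio scaling gave 3393 and 3358. Of the shared genes, 303 higher and 207 lower changed by at least 1 on the log2 scale with both. AHNAK, singled out after its values were seen, was the 1 gene called in opposite directions, at 54.6 FPKM in scramble, 49.4 with siRNA 1 and 59.6 with siRNA 2. It kept these calls in 2 of 9 settings without 1 library, in which 0 to 7 genes had opposite calls. Across genes, the fold changes of both siRNAs had Pearson's r of 0.977, Spearman's rho of 0.950 and a covariance of 0.228. Simulated unchanged groups with the same controls gave a mean r of 0.50, a rho of 0.473, a covariance of 0.00249 and at most 1 shared gene. The simulation drew independent noise for each gene with no difference between groups. Its low number of shared genes was therefore set by construction and does not cover scramble libraries that differ as a group. The 3 scramble libraries were not split into separate controls for each siRNA, as 1 siRNA would have been left with a single control library, so anything that set them apart would enter both comparisons alike.

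**Figure D1:**
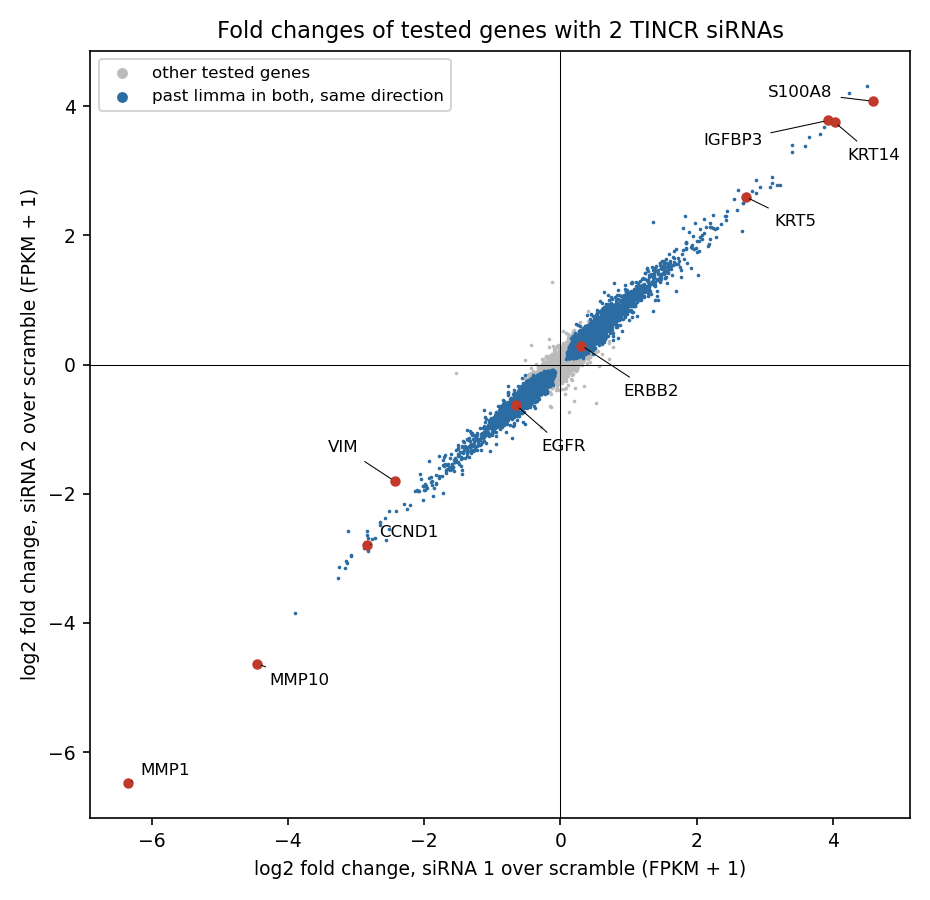
Log2 fold change over scramble (FPKM + 1) with siRNA 1 (horizontal) and siRNA 2 (vertical), one point per tested gene, blue where limma called both in the same direction. Points lie along the diagonal (Pearson's r = 0.977 across 12317 genes), from MMP1 at -6.35 and -6.48 to S100A8 at 4.58 and 4.08.

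Genes induced by ERK signalling fell together. Of 23 tested genes of this list, 2 rose and 20 fell with each siRNA, over all genes and adjusted over the list alone, with camera adjusted p = 6.97e-12 and 3.43e-12. The call held with an estimated correlation (adjusted p = 0.00636 and 0.00593). CCND1 (gene ID 595, chromosome 11, 69641105 to 69654474), which drives entry into the cell cycle, fell from 109 ± 2.84 to 14.3 ± 0.313 and 14.8 ± 0.250 FPKM. FOSL1, a subunit of AP-1, fell from 186 ± 7.26 to 31.5 ± 0.568 and 37.6 ± 0.875, and ETV4 fell from 31.01 ± 1.42 to 6.86 ± 0.223 and 7.69 ± 0.348. The genes of the RAS-RAF-MEK-ERK kinases themselves did not pass camera (adjusted p = 0.318 and 0.336), with 3 higher and 6 lower of 19 with siRNA 1, and 4 and 7 with siRNA 2. PI3K-AKT-mTOR genes did not pass camera (adjusted p = 0.464 and 0.425), with 5 higher and 6 lower of 21 with siRNA 1, and 3 and 4 with siRNA 2.

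Interferon-stimulated genes rose. With siRNA 1, 24 of 32 rose and 0 fell, 25 and 0 adjusted over the list alone, and with siRNA 2, 27 rose and 0 fell, the same adjusted over the list alone. The list passed camera (adjusted p = 8.12e-06 and 6.25e-06) and held with an estimated correlation (adjusted p = 0.0219 and 0.0192). Quantile normalization gave 23 higher and 1 lower with siRNA 1. MX1, an antiviral GTPase, rose from 1.87 ± 0.215 to 6.41 ± 0.203 and 6.28 ± 0.119 FPKM. SAMD9L rose from 0.53 ± 0.035 to 3.40 ± 0.218 and 3.61 ± 0.208, and OAS1 from 0.573 ± 0.076 to 2.54 ± 0.130 and 2.64 ± 0.222.

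Keratinocyte differentiation genes rose, 18 of 24 against 3 that fell with siRNA 1 (20 and 3 adjusted over the list alone) and 17 against 3 with siRNA 2 (17 and 3 adjusted over the list alone). They passed camera (adjusted p = 0.000184 and 0.000507), but not with an estimated correlation (adjusted p = 0.0923 and 0.111 with an estimated correlation). S100A9 rose from 503 ± 27.6 to 2456 ± 136 and 1968 ± 21.8 FPKM, and KRT13 from 0.22 ± 0.056 to 10.1 ± 0.632 and 7.41 ± 1.07. KRT80 fell, from 40.2 ± 2.34 to 27.6 ± 1.25 and 35.8 ± 0.562. The data held 36 genes of this list, and those other than the 24 tested were below the filter. Among them, LOR, KRT1 and LCE3D were at no more than 0.1 FPKM in any library. CALML5 was at 0.0 to 0.07 FPKM in scramble and 0.13 to 0.6 with siRNA. Mesenchymal transition genes fell, 14 of 20 against 3 that rose with siRNA 1 and 4 with siRNA 2, with the same counts adjusted over the list alone (camera adjusted p = 7.99e-06 and 9.45e-06). With an estimated correlation they did not pass (adjusted p = 0.0802 and 0.102 with an estimated correlation). FN1, fibronectin, fell from 514 ± 26 to 126 ± 2.32 and 139 ± 3.58 FPKM, and the hyaluronan receptor CD44 fell from 208 ± 4.19 to 59.8 ± 1.30 and 60.5 ± 1.01.

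Cholesterol and fatty acid synthesis genes rose, 25 of 30 against 2 that fell with siRNA 1 (camera adjusted p = 0.000166) and 21 against 3 with siRNA 2 (camera adjusted p = 0.0208). The call was lost with an estimated correlation (adjusted p = 0.0802 and 0.199 with an estimated correlation). HMGCS1, an early enzyme of the pathway, rose from 39.3 ± 1.57 to 65.1 ± 1.63 and 58.0 ± 1.69 FPKM, and FDFT1, squalene synthase, from 94.0 ± 6.30 to 179 ± 8.27 and 154 ± 1.52. Targets of miR-503 and the miR-16 family fell, 15 of 28 against 5 that rose with siRNA 1 and 14 against 6 with siRNA 2 (camera adjusted p = 0.00873 and 0.0208). This was lost with an estimated correlation (adjusted p = 0.0802 and 0.111 with an estimated correlation). SMURF2 fell from 78.1 ± 1.18 to 25.4 ± 0.570 and 25.5 ± 1.2 FPKM, and CCND1 and EGFR are members of this list too. Adjusted over the list alone, the counts of both lists were the same as over all genes with each siRNA.

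NF-kB and inflammatory genes fell, 12 of 22 against 5 that rose with siRNA 1 and 14 against 6 with siRNA 2 (camera adjusted p = 0.0299 and 0.00864). Adjusted over the list alone the counts lower were 12 and 15. With an estimated correlation the list did not pass (adjusted p = 0.136 and 0.103 with an estimated correlation), and with median-ratio scaling siRNA 1 no longer passed camera (adjusted p = 0.0683). PTGS2, the inducible cyclooxygenase, fell from 109 ± 7.64 to 15.1 ± 1.11 and 15.9 ± 0.863 FPKM, whereas TNFAIP2 rose from 29.2 ± 1.38 to 82.5 ± 1.83 and 76.3 ± 4.07. Of 12 fibroblast markers 8 were below the filter, among them FAP, at 0.14 to 0.18 FPKM in scramble and 0.0 to 0.08 with siRNA, COL6A3, at 0.14 to 0.2 and 0.01 to 0.03, and PDGFRB, at 0.04 to 0.08 and 0.27 to 0.47. Of the 4 tested, 4 rose with each siRNA, also adjusted over the list alone (camera adjusted p = 0.0202 and 0.021), which was lost with an estimated correlation (adjusted p = 0.202 and 0.199 with an estimated correlation). LUM rose from 0.497 ± 0.119 to 4.97 ± 0.384 and 4.01 ± 0.355 FPKM, and FBLN1 from 66.6 ± 3.27 to 103 ± 2.08 and 99.4 ± 2.58.

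With siRNA 1, 27 of 39 nuclear genes of oxidative phosphorylation rose and 2 fell (camera adjusted p = 0.00959), and 32 of 52 ribosomal protein genes rose and 0 fell (camera adjusted p = 0.0202). Neither held with an estimated correlation (adjusted p = 0.613 and 0.671 with an estimated correlation). With siRNA 2 the counts were 23 and 1, and 21 and 0, and neither passed camera (adjusted p = 0.154 and 0.251). Adjusted over the list alone, 17 ribosomal protein genes rose and 0 fell with siRNA 2, and the other 3 pairs of counts were the same. Median-ratio scaling gave 19 higher and 1 lower ribosomal protein genes with siRNA 1, and 7 and 2 with siRNA 2, and the list then no longer passed camera with siRNA 1 (adjusted p = 0.105). COX7B rose from 182 ± 14.2 to 270.1 ± 9.72 and 246 ± 1.57 FPKM.

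The other lists did not pass camera with either siRNA, and their counts adjusted over the list alone differed from those over all genes by at most 1. Of 39 S phase genes 20 rose and 4 fell with siRNA 1, and 20 and 10 with siRNA 2. Of 40 mitosis genes 21 rose and 5 fell, and 23 and 10, which median-ratio scaling turned to 15 and 7, and 16 and 15. Among CDK inhibitors and G1 regulators 3 rose and 7 fell of 16 with siRNA 1, and 6 and 7 with siRNA 2. Of 25 p53 targets 10 rose and 8 fell, and 10 and 7. Of 25 apoptosis regulators 9 rose and 10 fell with each siRNA, with BMF rising from 3.27 ± 0.218 to 14 ± 0.831 and 12.3 ± 0.162 FPKM and BCL2L1, on chromosome 20, falling from 124 ± 2.58 to 46.5 ± 0.732 and 44.9 ± 0.930. Of 28 stress response genes 19 rose and 5 fell, and 17 and 4, with camera adjusted p = 0.0721 and 0.0862. Of 20 epithelial adhesion genes 8 rose and 5 fell, and 9 and 6, with ELF3 rising from 5.51 ± 0.575 to 37.0 ± 0.765 and 37.4 ± 0.670 FPKM. Hypoxia and glycolysis genes went both ways, with 12 higher and 12 lower of 29 with siRNA 1, and 10 and 14 with siRNA 2.

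Counts with siRNA 1 and then siRNA 2, higher and lower, were 9 and 5, and 9 and 3, of 17 FOXO and insulin pathway genes. JAK-STAT genes gave 10 and 4, and 9 and 4, of 19. Heat shock and oxidative stress genes gave 10 and 11, and 10 and 7, of 22, with HSPB1 rising from 65.8 ± 1.56 to 251 ± 4.70 and 235 ± 6.54 FPKM. Estrogen receptor targets gave 4 and 6, and 5 and 6, of 12. The ERBB2 amplicon neighbours gave 9 and 4, and 7 and 4, of 17, with GSDMB at 3.05 FPKM in scramble and 7.90 and 7.87 with the siRNAs. Histone genes gave 3 and 6, and 2 and 7, of 13, small RNA pathway genes 2 and 4 of 13 with each, and DNA methyltransferases and TET enzymes 4 and 2 of 7 with each. Luminal markers gave 7 and 5, and 7 and 4, of 13, with KRT19 rising from 688 ± 35.2 to 1665 ± 74.0 and 1555 ± 37.7 FPKM. Basal and myoepithelial markers gave 10 and 6, and 11 and 6, of 18. Of 6 leukocyte markers 1 rose and 1 fell with each siRNA. Of the endothelial markers only EGFL7 was tested, at 1.36 FPKM in scramble and 0.89 and 1.01 with the siRNAs, and 0 erythroid or hepatic markers and 0 mitochondrially encoded genes were tested. Median, mean and camera direction differed in sign, none of them past camera, for p53 targets, apoptosis regulators, hypoxia and glycolysis, heat shock and leukocyte markers with both siRNAs. They also differed for PI3K-AKT-mTOR genes with siRNA 1 and for ERBB receptors, CDK inhibitors and DNA methyltransferases with siRNA 2.

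**Figure D2:**
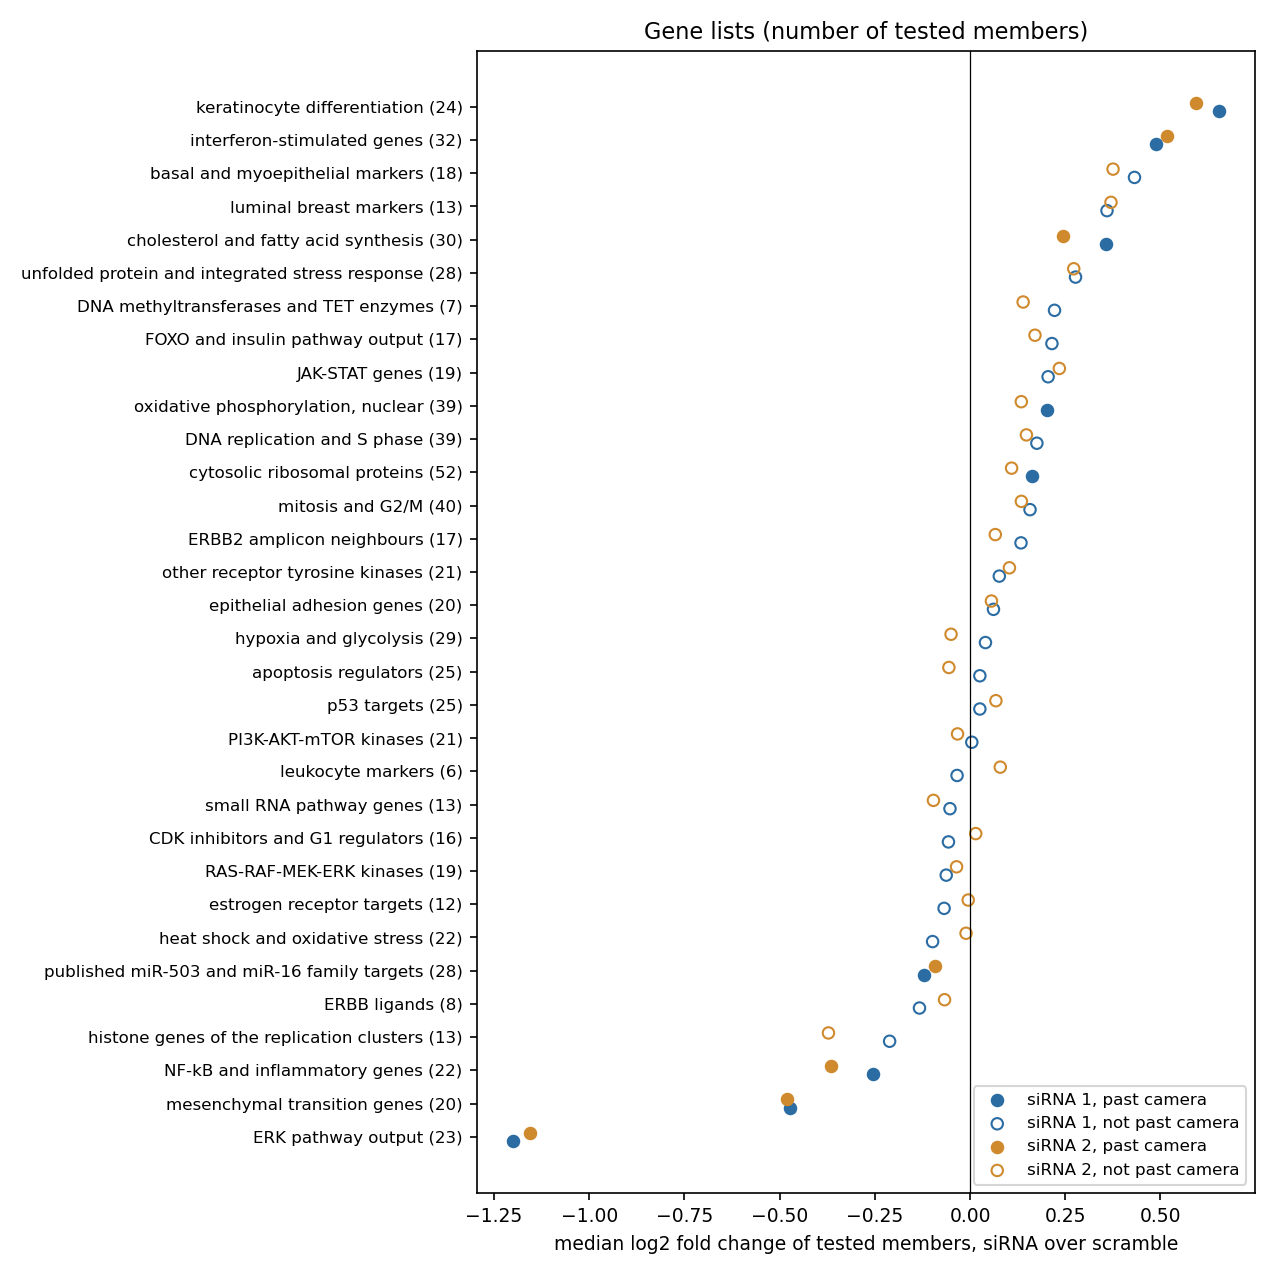
Median log2 fold change over scramble of each gene list with at least 5 tested members, for both siRNAs, with filled points where the list passed camera at its preset correlation; with an estimated correlation 2 lists passed with each siRNA. The ERK pathway output list lies lowest, at -1.20 with siRNA 1 and -1.15 with siRNA 2.

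**Figure D3:**
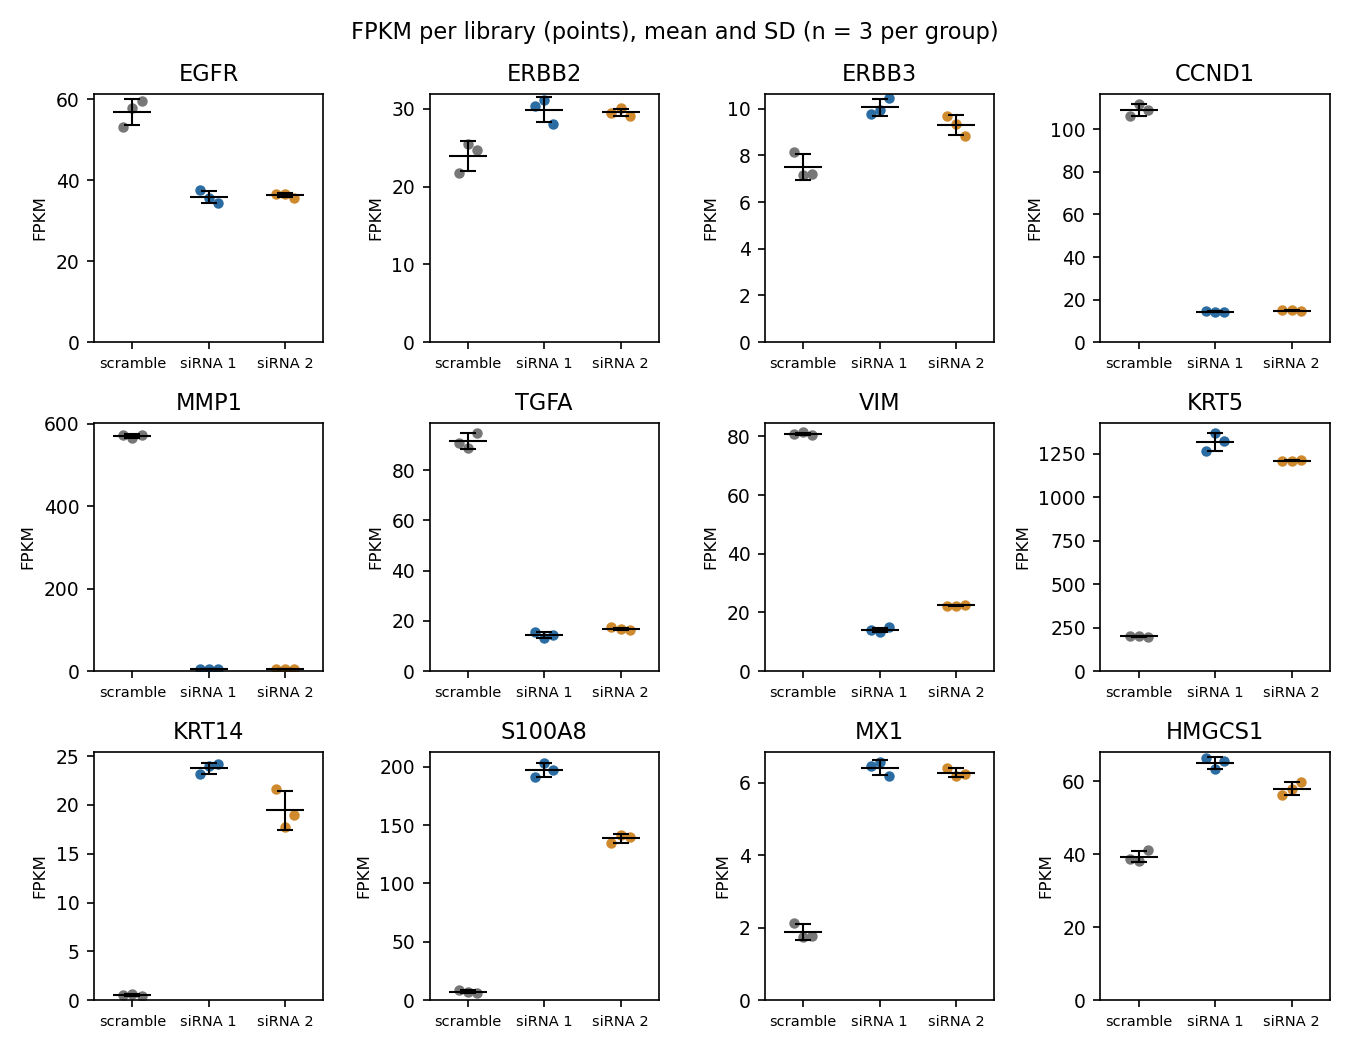
FPKM of 12 genes in each of the 9 libraries, with the mean and SD of each group of 3, on axes that start at 0. EGFR falls from a mean of 56.9 to 35.9 and 36.3, and S100A8 rises from 7.33 to 197 and 139.

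Long stretches of neighbouring genes shifted together, measured as log2 fold change over scramble minus the median of all genes. On chromosome 2, the 571 tested genes before OLA1, which starts at 174072447 (GRCh38.p12), had a median shift of -0.35 with siRNA 1 (95% bootstrap interval -0.38 to -0.31) and -0.34 with siRNA 2 (-0.37 to -0.30), or linear ratios of 0.787 and 0.793 of siRNA to scramble relative to the median gene. The 255 genes after that edge were at 0.06 with each siRNA. The edge was fitted to these same fold changes. The intervals in this paragraph resample genes, so they leave out the choice of the region and the spread between libraries. On chromosome 20, 317 genes had a median shift of -0.26 (-0.29 to -0.22) and -0.28 (-0.31 to -0.25). TGFA, GPAT2, CYP1B1, IL1R2 and IL1B lie on the shifted part of chromosome 2, and TGM2, PI3 and BCL2L1 on chromosome 20. In windows of 50 genes, 20 of 457 went, for the mean of both siRNAs, beyond the largest window of 1000 shuffles of gene positions, in 5 runs on chromosomes 2 and 20, all lower. On chromosome 20 the runs covered 5.94 to 25.23 Mb (50 genes) and 47.50 to 63.57 Mb (75 genes), and no run covered the stretch between them. Chromosome 9 had a smaller median shift of -0.12 and -0.10 over 503 genes, without such a window. The SD of window medians was 0.118 with siRNA 1 and 0.114 with siRNA 2, against shuffled means of 0.0514 and 0.0507 (permutation p = 0.001 each, the smallest the shuffles can give). The direct comparison of both siRNAs gave the same permutation p = 0.001 (SD 0.0337 against 0.0162, 2 windows beyond its shuffles). Shuffling treats neighbouring genes as independent, and this p is not particular to the comparisons with scramble. Without the genes of both chromosomes, 4474 genes were higher and 2418 lower with siRNA 1, and 4503 and 2399 with siRNA 2.

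**Figure D4:**
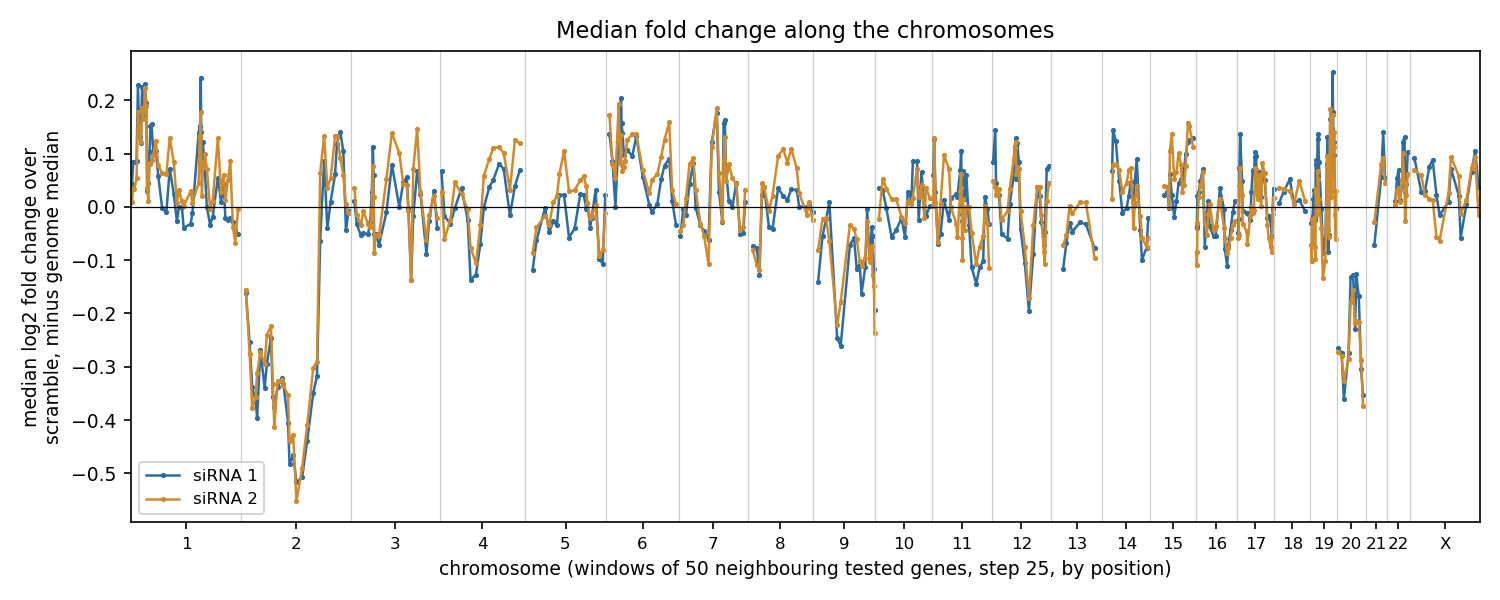
Median log2 fold change over scramble, minus the genome median, in windows of 50 neighbouring genes along the genome (GRCh38.p12) for both siRNAs. For the mean of both siRNAs, the 20 windows beyond the shuffles all lie on chromosomes 2 and 20. Medians over the genes of chromosome 2 before 174.07 Mb and of chromosome 20 were -0.35 and -0.26 for siRNA 1.

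The direct comparison of both siRNAs asked where their effects differed. VIM (gene ID 7431, chromosome 10, 17227935 to 17237593), the intermediate filament of mesenchymal cells, was at 80.9 ± 0.412 FPKM in scramble, 14.2 ± 0.696 with siRNA 1 and 22.4 ± 0.124 with siRNA 2, a log2 difference of 0.63 (SE 0.039, limma adjusted p = 2.25e-05). PI3, an elastase inhibitor of epithelia, was at 17.8 ± 0.394 FPKM with siRNA 1 and 9.38 ± 0.526 with siRNA 2 (log2 difference -0.86, limma adjusted p = 0.00775). S100A8 was lower with siRNA 2 than with siRNA 1, at 139 against 197 FPKM (adjusted p = 0.0181). Unlike the call of VIM, those of PI3 and S100A8 were each lost under at least 1 alternative setting. In limma, 34 genes were higher and 38 lower with siRNA 2. None changed by at least 1 on the log2 scale in limma (0 genes), while 2187 genes had an unadjusted p under 0.05. Without scramble replicate 1 the count was 126, and without siRNA 1 replicate 2 or 3 it was 5, and without siRNA 2 replicate 1, 2 or 3 it was 3, 8 and 2.

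Cholesterol and fatty acid synthesis genes were lower with siRNA 2 than with siRNA 1, 3 of 30 over all genes and 16 adjusted over the list alone (camera adjusted p = 7.37e-11, and 0.0308 with an estimated correlation). DHCR7 was at 40.5 ± 2.22 FPKM with siRNA 1 and 32.9 ± 0.546 with siRNA 2, and SCD at 90.4 ± 1.76 and 79.2 ± 0.111. Of 34 lists, 9 passed camera in this comparison and 1 passed with an estimated correlation. Of 24 keratinocyte differentiation genes 1 was higher and 4 were lower (camera adjusted p = 0.00073, adjusted p = 0.181 with an estimated correlation), and of 22 NF-kB genes 0 were higher and 2 lower (camera adjusted p = 0.000565, adjusted p = 0.065 with an estimated correlation). The gene lists of S phase, mitosis, oxidative phosphorylation, ribosomal proteins, histones and heat shock also passed camera, with adjusted p from 0.000576 to 0.0347, and none of them did with an estimated correlation (adjusted p = 0.18 to 0.591 with an estimated correlation).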

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

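All tests of explanations here were chosen only after the pattern they address was seen; of the 75th percentile test of the chromosome 2 genes only the value itself had not been seen.

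A test of the difference between both siRNAs called 72 genes, and 2 to 126 without 1 library. Of 29 named genes called, 28 lost this call under at least 1 setting, all but VIM, so the values that follow for the genes other than VIM are weakly supported. The log2 difference, siRNA 2 minus siRNA 1, was 0.63 for VIM, 0.54 for IL1R2, 0.44 for C19orf71, 0.40 for ARRDC4, 0.38 for LGALS3, 0.36 for KRT80, 0.36 for RNASE7 and 0.33 for MYEF2. It was -0.86 for PI3, -0.64 for RHOV, -0.59 for LY6D, -0.53 for SPRR1B, -0.53 for CCL2, -0.51 for S100A8, -0.44 for HOTS and -0.43 for AMTN. HOTS overlaps H19 on the opposite strand, so reads of either can be taken for the other. Groups of 3 libraries were not tested for single libraries that stand apart.

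Genes of chromosome 2 before OLA1 shifted together by -0.35 and -0.34 with the siRNAs. Removing the trend of fold change on GC content and transcript length left -0.35 (-0.349), which argues against that bias as the cause. The whole distribution moved, with the 75th percentile shifting by 97.6% of the shift of the median, so a copy number difference between the scramble cells and the siRNA cells is a candidate explanation. An earlier form of that test, the share of genes below the genome median (81.4%), was set aside because the choice of the region nearly fixes it. The labels name 2 sources of the line without saying which libraries came from which, and no DNA was measured.

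With both siRNAs, 6729 of 12317 tested genes passed in the same direction. Median-ratio scaling gave 6751, with 5965 of the 6729 kept in direction, which argues against scaling as the whole cause. Subtracting the regional median gave 6609, with 5403 kept and 13 reversed. Of the shared genes, 771 lie on chromosomes 2 and 20, and 5939 stayed called among the 11174 tested genes outside those chromosomes. Most tested genes lie outside them, so this count was nearly fixed in advance. It shows only where most shared genes lie and does not test copy number as a cause. The regional subtraction cannot decide on smaller copy number changes or on indirect effects of copy number. A separate handling or origin of the scramble libraries cannot be told apart from the siRNAs, since 0 labels name a batch, day or culture, and a difference between cell populations may therefore contribute to any gene shared by both siRNAs. A common effect of losing TINCR is the biological explanation that the design gives, and it stays open and untested, as TINCR itself had no value.

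ERBB2 was at 24.0 FPKM in scramble, although the line is described as ERBB2-amplified. This was the 72.3 percentile of the 12262 tested genes used in the window scan, which leaves out genes below the filter. STARD3, PGAP3, ERBB2, MIEN1 and GRB7 as a run of 5 neighbours lay at the 57.7 percentile of all such runs. Cells of a line or subline without ERBB2 amplification may explain this level, and the labels do not decide it. No biological explanation was tested.

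Each 6-library comparison has 10 splits, too few for a share under 0.05. The real splits gave 7766, 7759 and 72 genes and the highest other split gave 0 each time, with 1 of 10 splits as large. In the comparisons with scramble, each other split mixed scramble with siRNA libraries, which widens the spread within groups. Their 0 was therefore nearly fixed and says nothing about the cause of the difference. For shared genes, 1 of 100 drawn splits of the 9 libraries was as large as the real 6729, and the highest other gave 6687. The 5 drawn splits that kept the scramble libraries in one group ranged from 0 to 6687, and the 94 that divided them gave 0 each, so these splits show only that the scramble libraries stand apart and give no share for the siRNAs.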

How the results depend on the processing

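The settings median-ratio scaling, quantile normalization, regional median subtracted and the one without chromosomes 2 and 20 were chosen only after the results were seen; the others were planned. Genes called with siRNA 1, siRNA 2 and both stayed within 1.5 times of 7766, 7759 and 6729 except under a minimum log2 change of 1 (572, 560 and 510). Leaving out 1 library gave 7257 to 7659, 7073 to 7741 and 6280 to 6548. The count between both siRNAs, 72, was 3 with no filter, 230 with the 6 libraries alone, 2 at an adjusted p under 0.01, 46 after subtracting the regional median, 0 with a minimum log2 change of 1 (limma, 2187 at an unadjusted p under 0.05), and 2 to 126 without 1 library. With the replicate block it was 6; replicate numbers did not pair the libraries (residual r of -0.16 to 0.14 at the same number), so that value carries no weight. The correlation of fold changes, 0.977, was 0.973 with a pseudocount of 0.1, 0.972 with no filter and 0.970 to 0.977 without 1 library. Lists past camera numbered 10, 8 and 9, and 2, 2 and 1 with an estimated correlation; median-ratio scaling left 8 with siRNA 1, without NF-kB and ribosomal proteins (adjusted p = 0.0683 and 0.105); fry gave 27 and 27 for the siRNAs against scramble, and without 1 library the counts were 9 to 11, 8 to 10 and 7 to 9. RRM1 (-0.026) and TOP2A (-0.076) reversed in sign with siRNA 1 after subtracting the regional median and were then not called (adjusted p = 0.686 and 0.181). Except where a setting itself tests fewer genes or libraries, the cause was not tested. EGFR kept its call in 18 settings, from -0.72 to -0.62 and from -0.70 to -0.60. Of other named genes called, 209 of 253, 204 of 256 and 1 of 29 (VIM, 0.59 to 0.66) kept their call in all 18 settings that recomputed single genes, and 24 and 25 more were untested in at least 1 of these and kept it in the rest. The minimum log2 change of 1 and the adjusted p under 0.01 are not among these settings, and VIM and EGFR lie below that minimum change. Count-based tests and their scaling factors were not run, since the values were FPKM, and the TINCR check gave no value under any alternative. Without read totals, what depth limits is unknown.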

Other observations

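The gene groups here were chosen only after their values were seen, and no tests of explanations were run on them. Of 20 genes known as targets of YAP and TEAD, 15 fell with each siRNA in limma, and 3 rose with siRNA 1 and 4 with siRNA 2. CTGF fell from 7.94 to 1.08 and 1.32 FPKM, CYR61 from 42.2 to 12.2 and 13.5, and NT5E from 113 to 14.9 and 17.3. IGFBP3, whose large rise is given above, is among the members that rose.

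Of 12 tested matrix metalloproteinases, 6 rose and 4 fell with each siRNA in limma. MMP3 and MMP9 were below the filter and not counted, and both were lower in the siRNA libraries. MMP3 was at 0.71 to 0.83 FPKM in scramble and 0.0 to 0.06 with siRNA, and MMP9 at 0.15 to 0.22 and 0.0 to 0.02. MMP1 and MMP10, whose large falls are given above, were among the 4 that fell. MMP28 rose from 9.20 to 41.9 and 38.3 FPKM, MMP7 from 0.58 to 5.46 and 4.34, and MMP14 fell from 219 to 154 and 157. Of 7 serpin genes in the cluster on chromosome 18, 5 rose and 2 fell, with SERPINB4 rising from 0.577 to 12.6 and 9.98 FPKM and SERPINB8 falling from 43.6 to 23.6 and 23.6. All 4 tested SPANX genes rose, with reads that cannot be placed with certainty among their copies.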
